A study of Mus musculus with 10 samples.

How the data were processed

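The samples were RNA from B cells of mouse spleen, isolated with a magnetic kit and kept in medium, with anti-IgM, or with anti-IgM and PGE2. Total RNA was purified on columns, amplified with T7 polymerase, labelled with Cy3 and Cy5 and hybridised to mouse oligonucleotide arrays. Each of 5 comparisons was run on 2 arrays with the dyes exchanged, giving 10 arrays. The deposited values were taken as log2 ratios of the channels, normalised by the authors with a method not given in the sources used here. Base 10 was excluded, because the lowest value, -9.03, exceeds in size the 4.82 that a 16-bit scanner can give. Natural logs could not be excluded, since that range is 11.1 in them. The direction was taken as Cy5 over Cy3, which is likely from the immediate-early genes but was not given. Signal intensities, background and probe sequences were not analysed here.

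Ratios were turned by the dyes in the labels to numerator over denominator. Of all probes, 21111 carried 1 gene symbol and 4233 none. Symbols were current for 17069 probes, were updated through synonyms of the mouse reference for 3974 and were kept for 68. Probes with the same symbol were averaged on each array, which gave 18300 genes, of which 16299 had 1 probe and 2001 more than 1. Probes without a symbol stayed single, and 22533 features were tested. Actb and Gapdh had 257 probes each. No value was missing and no filter on low values was possible without intensities. The values are ratios, so no depth was known and the number of arrays limited the precision.

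All arrays entered 1 limma fit with 5 group coefficients and a dye effect for each feature. Residual degrees of freedom were 4, prior degrees of freedom 3.13 and the prior variance 0.00646. Standard errors are those of this fit, with 1 spread per feature estimated over all arrays after the dye effect. They are not the spread between the arrays of a single comparison. A set of 8 contrasts was tested, with Benjamini-Hochberg adjustment over 22533 features and a limit of 0.05. They were the 5 comparisons, the difference of the anti-IgM responses between genotypes, that of the PGE2 responses, and the genotypes without PGE2 through the chain of 24 h arrays. Features at least 2-fold changed on both arrays were counted without a test, against the same count with 1 array left unturned. When an array was left out, the lone array of its pair was assumed to vary like the other groups. On simulated data of this design, 2-fold changes were recovered in 80.6% to 100% of cases and 1.5-fold changes in 41.8% to 95.5%. At 1.5-fold, recovery was lowest for the genotypes without PGE2 and for the difference of the PGE2 responses (46.3%). False calls were 2.54% to 6.44% of all calls. The simulation changed few features and drew independent noise from the fitted spread. It held no effects of RNA extracts, correlated genes or single-array outliers, so its share of false calls need not hold for these data.

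The named genes were Ptger4 and, per contrast, the 10 with the largest rise and the 10 with the largest fall among called genes with a formal symbol and the same sign on all arrays compared. With under 5 called in a direction, the 5 largest values were given as values. In each list described, the 2 members with the smallest p in each direction were eligible as examples. Which of these examples the text names was decided after their values were seen, mostly taking those that kept their call when any array was left out, so the examples look steadier than the lists.

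The 19 gene lists covered immediate-early genes, NF-kB targets, activation and antigen presentation, cyclic AMP and CREB targets, the prostaglandin pathway, DNA replication, mitosis, ribosome biogenesis and Myc targets, glycolysis, cholesterol synthesis, quiescence and homing, B cell identity, plasma cells, interferon response, p53 and apoptosis, heat shock and folding, hypoxia and amino acid stress, JAK-STAT feedback, and MAPK and B cell receptor regulators. A further 7 held markers of T cells, NK cells, monocytes and macrophages, neutrophils, dendritic cells, red cells and platelets. Lists were tested with camera at a preset correlation of 0.01, adjusted over all lists of a contrast, with an estimated correlation beside it, and with fry. With an estimated correlation, camera tests on the 4 residual degrees of freedom. After adjustment over the lists such a test can hardly pass, so its lack of calls decides nothing. The comparisons, tests, gene lists, rule for named genes and most alternatives were fixed before the data were examined. Alternatives were fits without the dye term, centred arrays, centred and scaled arrays, single probes, only the arrays compared, a minimum fold of 1.5 by limma's treat, a limit of 0.01 and leaving out each array. Dropping features with disagreeing arrays and reading the values as natural logs were chosen after seeing the data. Overlaps were tested with Fisher's exact test on both sides and correlations across features carry no p.

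The versions were R 4.3.3, limma 3.58.1, Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9.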

Results

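RNA of mouse splenic B cells was compared on 10 oligonucleotide arrays with 2 colours, in 5 comparisons of 2 arrays each. The cells came from female mice aged 2 months, labelled Ptger4+/+ or Ptger4-/-. Ptger4 encodes a receptor for prostaglandin E2 (PGE2) that signals through cyclic AMP. Antibody fragments against IgM (anti-IgM) were used to engage the B cell receptor. In each genotype, anti-IgM for 2 h was compared with medium, and anti-IgM with PGE2 for 24 h was compared with anti-IgM alone. The fifth comparison set cells labelled Ptger4-/- against Ptger4+/+ cells, both given anti-IgM and PGE2 for 24 h. In each pair of arrays the dyes were exchanged between the RNAs compared. Every array gave a log ratio for each probe, with 0 missing values, and the array medians lay between 0.000895 and 0.0148. Array values carry no read depth, and 2 arrays per comparison limited the precision. Whether the exchanged arrays held the same RNA extracts was not given in the sources used here, so the p-values can cover technical spread alone.

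The direction of the ratios and their log base were not given in the sources used here. On the reading of Cy5 over Cy3, 8 of 22 measured immediate-early genes of B cell receptor stimulation were at least 2-fold higher with anti-IgM on both arrays of Ptger4+/+ cells and 1 was lower. In the cells labelled Ptger4-/-, 9 were higher and 1 was lower. That direction is therefore likely, and the rise of those genes is no finding of its own. Ptger4, the gene named by the genotype labels, was measured by 1 probe. Its log2 ratio with anti-IgM was 1.08 and 0.74 on the arrays of Ptger4+/+ cells (mean 0.91 ± 0.07, standard error, n = 2 arrays, limma adjusted p = 7.22e-05). It was 0.59 and 0.53 on the arrays labelled Ptger4-/- (mean 0.56 ± 0.07, limma adjusted p = 0.000708). Standard errors here and below are those of the limma fit. Their spread is estimated over all arrays together, not from the arrays of the comparison alone. With PGE2 the Ptger4 ratio was -0.59 ± 0.07 in Ptger4+/+ cells (limma adjusted p = 0.000964) and 0.04 ± 0.07 in cells labelled Ptger4-/- (limma adjusted p = 0.933). Between the genotypes with PGE2 it was 0.46 and 0.52 on the arrays, higher in RNA labelled Ptger4-/- (mean 0.49 ± 0.07, limma adjusted p = 0.00207). The probe thus showed no loss of signal in the RNA labelled Ptger4-/-. The probe's place in the gene was not given in the sources used here, and a probe outside the deleted part checks nothing.

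**Figure D1:**
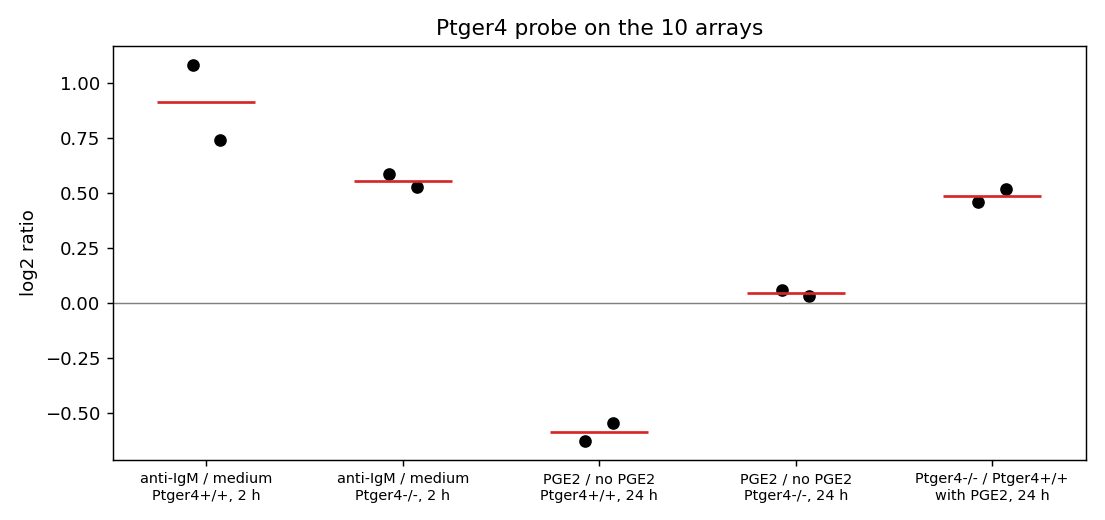
Turned log2 ratio of the Ptger4 probe on each of the 10 arrays (points) and the mean of each pair (bar), by comparison. The ratio lay at 0.46 and 0.52 where RNA labelled Ptger4-/- was compared with Ptger4+/+ RNA.

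In Ptger4+/+ B cells, anti-IgM for 2 h raised Ccl3, Ccl4, Egr2 and Myc among others and lowered Ltb, S1pr1 and Il10ra. This comparison gives the early response to the B cell receptor. The chemokine genes Ccl3 and Ccl4 had log2 ratios of 3.76 ± 0.08 and 3.39 ± 0.13 (standard error of the fit over all arrays, mean of n = 2 arrays). The arrays gave 3.93 and 2.84 for Ccl4, further apart than that standard error conveys. Egr2 at 3.21 ± 0.06 and Egr1 at 2.49 ± 0.08 encode immediate-early transcription factors, Myc at 2.60 ± 0.04 drives cell growth, and Gfi1 at 2.59 ± 0.12 encodes a transcriptional repressor. The peptide transporter gene Slc15a3 rose by 2.72 ± 0.11, and Nampt, whose product makes an NAD precursor, by 2.46 ± 0.08. Hilpda, a lipid droplet gene, rose by 2.50 ± 0.06 and Marcksl1 by 2.50 ± 0.09. Among the falls, Ltb, encoding lymphotoxin beta, had a log2 ratio of -2.91 ± 0.05. S1pr1, whose product guides lymphocytes out of lymphoid organs, stood at -2.82 ± 0.06 and the interleukin-10 receptor gene Il10ra at -2.53 ± 0.06. Sting1, an adaptor of DNA sensing, fell to -2.59 ± 0.06, the homeobox gene Hhex to -2.55 ± 0.05 and Mylip, whose product degrades the LDL receptor, to -2.65 ± 0.07. Snx20 stood at -2.64 ± 0.05, Arhgap45 at -2.52 ± 0.04, the cytokine gene Il16 at -2.50 ± 0.04 and the ribonuclease gene Rnase6 at -2.49 ± 0.07. All 20 passed the limma test, with the highest adjusted p of them, 1.07e-05, at Gfi1. Of 22533 features, limma called 2188 higher and 2561 lower, and 229 and 234 were at least 2-fold higher or lower on both arrays (6 in all when 1 array was left unturned). Without replicate 1 the calls fell to 3024.

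Genes of ribosome biogenesis and Myc targets moved most uniformly among the lists of this comparison, with 28 of 29 measured members rising and 1 not passing (29 adjusted over the list alone). Ppan stood at 1.53 ± 0.06 and the RNA polymerase I subunit gene Polr1b at 1.87 ± 0.09. Camera gave adjusted p = 2.15e-21 with the preset correlation and adjusted p = 0.185 with an estimated correlation. Of 21 NF-kB target genes, 17 rose, 2 fell and 2 did not pass (17 higher and 2 lower adjusted over the list alone), with Nfkbiz at 2.12 ± 0.06, the adhesion gene Icam1 at 1.56 ± 0.05 and, among the falls, Bcl3 at -0.64 ± 0.09. Camera gave adjusted p = 2.01e-11 with the preset correlation and adjusted p = 0.139 with an estimated correlation for this list. Immediate-early genes rose in 13 of 22 cases, while 3, among them Btg2 at -1.11 ± 0.05 and Dusp6 at -0.97 ± 0.06, fell (14 higher and 3 lower adjusted over the list alone). For immediate-early genes, camera gave adjusted p = 1.21e-07 with the preset correlation and adjusted p = 0.185 with an estimated correlation. The sign of the ratios was chosen by this list, so its direction is no finding of its own. Among genes of heat shock and protein folding 12 of 16 rose and 0 fell (14 higher and 0 lower adjusted over the list alone), led by Hspa9 at 1.34 ± 0.06 and Hspd1 at 1.28 ± 0.09. For heat shock genes, camera gave adjusted p = 4.84e-08 with the preset correlation and adjusted p = 0.189 with an estimated correlation. The hypoxia and amino acid stress list had 14 rises and 2 falls among 19 genes (15 higher and 2 lower adjusted over the list alone), with the one-carbon enzyme gene Mthfd2 at 2.05 ± 0.05 and the amino acid transporter gene Slc7a5 at 1.89 ± 0.09. For the hypoxia list, camera gave adjusted p = 1.10e-07 with the preset correlation and adjusted p = 0.189 with an estimated correlation. Targets of cyclic AMP and CREB rose in 10 of 24 cases and fell in 2 (10 higher and 3 lower adjusted over the list alone), with Nr4a1 at 2.42 ± 0.07, Rgs2 at 1.49 ± 0.07 and the phosphodiesterase gene Pde4b at -0.81 ± 0.06. For cyclic AMP targets, camera gave adjusted p = 0.00851 with the preset correlation and adjusted p = 0.185 with an estimated correlation. Cholesterol synthesis genes included Idi1 at 1.52 ± 0.05 and Msmo1 at 0.75 ± 0.07, with 7 rises and 3 falls among 17 (10 higher and 4 lower adjusted over the list alone). For cholesterol synthesis, camera gave adjusted p = 0.0258 with the preset correlation and adjusted p = 0.584 with an estimated correlation. In the prostaglandin pathway 4 of 19 rose, among them Ptger4 and Ptges3 at 0.79 ± 0.06 (4 higher and 0 lower adjusted over the list alone). For the prostaglandin pathway, camera gave adjusted p = 0.00851 with the preset correlation and adjusted p = 0.189 with an estimated correlation.

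Quiescence and homing genes went the other way in Ptger4+/+ cells: 11 of 22 fell and 1 rose (1 higher and 13 lower adjusted over the list alone), with Cd55 falling to -1.14 ± 0.04 and the cytokine receptor gene Il7r rising by 0.38 ± 0.05. Camera gave adjusted p = 9.48e-07 with the preset correlation and adjusted p = 0.122 with an estimated correlation. B cell identity genes fell in 12 of 20 cases and rose in 3 (3 higher and 12 lower adjusted over the list alone), with the B cell receptor subunit gene Cd79b at -2.20 ± 0.06, Cd22 at -1.90 ± 0.08 and, as a rise, Cd72 at 1.53 ± 0.11. Camera gave adjusted p = 2.98e-05 with the preset correlation and adjusted p = 0.286 with an estimated correlation for that list. Camera made no call at 2 h in Ptger4+/+ cells for the remaining lists. Antigen presentation and activation genes showed 8 rises, Irf4 at 2.35 ± 0.07 and Batf at 1.13 ± 0.06 among them, and 4 falls among 20 (8 higher and 4 lower adjusted over the list alone). For the activation list, camera gave adjusted p = 0.0675 with the preset correlation and adjusted p = 0.498 with an estimated correlation, and without the dye term it called that list higher (adjusted p = 0.0142). Plasma cell genes showed 3 rises and 6 falls among 16 (3 higher and 7 lower adjusted over the list alone), with the endoplasmic reticulum chaperone gene Hspa5 at 1.23 ± 0.08 and Mzb1 at -2.01 ± 0.07. Glycolysis genes showed 6 and 2 among 18 (7 higher and 3 lower adjusted over the list alone), with Hk2 at 2.37 ± 0.08 and Pgam1 at 1.20 ± 0.05. DNA replication genes showed 1 rise, Ccnd2 at 1.10 ± 0.07, and 8 falls, Rpa1 at -0.67 ± 0.05 among them, in 34 (1 higher and 8 lower adjusted over the list alone). Mitosis genes showed 4 rises and 3 falls among 31, interferon response genes 3 and 5 among 23, and p53 and apoptosis genes 5 and 7 among 22. Of the JAK-STAT list 5 rose and 4 fell among 18, and of the regulators of MAPK and B cell receptor signalling 7 rose, Nfatc1 at 1.21 ± 0.07 among them, and 8 fell, Syk at -0.95 ± 0.06 among them, in 27.

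In cells labelled Ptger4-/-, anti-IgM for 2 h raised Ccl3, Ccl4 and Egr2 and lowered Il10ra, S1pr1 and Ltb. Ccl3 stood at 3.93 ± 0.08, Ccl4 at 3.84 ± 0.13 and Egr2 at 3.24 ± 0.06 (log2, standard error, n = 2 arrays). Nampt rose by 2.89 ± 0.08, Gfi1 by 2.69 ± 0.12 and Hilpda by 2.56 ± 0.06. Irf4 at 2.71 ± 0.07 encodes a transcription factor of activated B cells and plasma cells, Bhlhe40 at 2.57 ± 0.07 another transcription factor, and Plek at 2.65 ± 0.11 a protein kinase C substrate. Il10ra had a log2 ratio of -3.18 ± 0.06, S1pr1 of -3.09 ± 0.06, Sting1 of -2.99 ± 0.06 and Ltb of -2.97 ± 0.05. Il16 stood at -2.88 ± 0.04, Snx20 at -2.85 ± 0.05, Rasa3, a brake on Ras, at -2.57 ± 0.08, Neurl3 at -2.51 ± 0.13 and Cd79b at -2.51 ± 0.06. Optn and Cog7 also passed the test but rested on 1 array each, with 8.64 and 0.50 on the arrays for Optn and -0.68 and -5.53 for Cog7, and neither was called without the dye term (limma adjusted p = 0.0849 and 0.0524). These 20 genes passed with limma adjusted p up to 0.0474, that of Optn. Among 22533 features, 2622 were called higher and 2637 lower by limma, and 361 and 284 were at least 2-fold higher or lower on both arrays (6 in all with 1 array unturned).

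The lists of the cells labelled Ptger4-/- at 2 h followed. All 29 measured ribosome biogenesis and Myc target genes rose (29 higher and 0 lower adjusted over the list alone), with Ppan at 1.64 ± 0.06 and Odc1, which starts polyamine synthesis, at 1.73 ± 0.07. For ribosome biogenesis, camera gave adjusted p = 1.51e-21 with the preset correlation and adjusted p = 0.172 with an estimated correlation. NF-kB targets had 17 rises and 2 falls among 21 (17 higher and 2 lower adjusted over the list alone), with Nfkbiz at 2.01 ± 0.06 against Bcl3 at -1.28 ± 0.09. For NF-kB targets, camera gave adjusted p = 3.38e-09 with the preset correlation and adjusted p = 0.145 with an estimated correlation. Immediate-early genes had 14 rises and 3 falls among 22 (14 higher and 3 lower adjusted over the list alone), with Myc at 2.55 ± 0.04 against Dusp6 at -1.35 ± 0.06. For immediate-early genes, camera gave adjusted p = 7.04e-08 with the preset correlation and adjusted p = 0.172 with an estimated correlation. Here too the list had served to choose the sign of the ratios. Heat shock and folding genes had 12 rises and 0 falls among 16 (13 higher and 1 lower adjusted over the list alone), with Hspa9 at 1.47 ± 0.06 and Cct2 at 1.04 ± 0.05. For heat shock genes, camera gave adjusted p = 5.07e-08 with the preset correlation and adjusted p = 0.201 with an estimated correlation. Hypoxia and amino acid stress genes had 14 rises and 3 falls among 19 (14 higher and 3 lower adjusted over the list alone), with Slc7a5 at 2.02 ± 0.09 against Ndrg1 at -0.67 ± 0.06. For the hypoxia list, camera gave adjusted p = 9.50e-07 with the preset correlation and adjusted p = 0.201 with an estimated correlation. Activation and antigen presentation genes had 9 rises and 2 falls among 20 (9 higher and 2 lower adjusted over the list alone), with Cd74, the invariant chain of antigen presentation, at 1.31 ± 0.04 against Icosl at -1.86 ± 0.19. For the activation list, camera gave adjusted p = 0.000667 with the preset correlation and adjusted p = 0.201 with an estimated correlation. Targets of cyclic AMP and CREB had 10 rises and 2 falls among 24 (10 higher and 2 lower adjusted over the list alone), with Gpr183 at 2.06 ± 0.09 against Pde4b at -0.85 ± 0.06. For cyclic AMP targets, camera gave adjusted p = 0.00103 with the preset correlation and adjusted p = 0.145 with an estimated correlation. Quiescence and homing genes fell in 11 and rose in 4 of 22 (5 higher and 11 lower adjusted over the list alone), with Cd55 at -1.13 ± 0.04 against Ccr7 at 0.51 ± 0.07. For quiescence genes, camera gave adjusted p = 0.000667 with the preset correlation and adjusted p = 0.145 with an estimated correlation. B cell identity genes fell in 10 and rose in 3 of 20 (3 higher and 13 lower adjusted over the list alone), with Cd79a at -1.63 ± 0.06 against Spib at 0.83 ± 0.07. For B cell identity, camera gave adjusted p = 0.000548 with the preset correlation and adjusted p = 0.331 with an estimated correlation. Interferon response genes fell in 8 and rose in 2 of 23 (3 higher and 9 lower adjusted over the list alone), with Stat2 at -1.50 ± 0.05 and Gbp3 at -0.87 ± 0.08. For interferon response, camera gave adjusted p = 0.0172 with the preset correlation and adjusted p = 0.173 with an estimated correlation. Cholesterol synthesis genes, with 8 rises and 2 falls among 17, were not called by camera (adjusted p = 0.0520) but were called higher without the dye term (0.0246) and with centred arrays (0.0462).

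Set side by side, the anti-IgM responses of the genotypes correlated across genes. Across 22533 features, Pearson's r was 0.85 and Spearman's rho 0.65, with genes not being independent replicates. Both genotypes shared 1748 called rises and 1914 called falls, where independent lists would share 255 and 300. Their odds ratios were 88.2 and 78.7 by Fisher's exact test, with p below the smallest number the program could hold. Features are not independent in that test either, so its p measures no replication. The difference itself, tested as an interaction, passed for 391 features, of which 254 were higher and 137 lower in cells labelled Ptger4-/-. Cd74 differed by 1.66 ± 0.06 on the log2 scale, the cyclin-dependent kinase gene Cdk4 by 1.33 ± 0.08, the RNA helicase gene Ddx3x by 1.28 ± 0.09 and U2surp by 1.21 ± 0.10 (standard error, 2 arrays against 2, limma adjusted p up to 0.00977). Plagl2 differed by 1.20 ± 0.08, Capns1 by 1.20 ± 0.10, Il17ra by 1.14 ± 0.16, the ATP synthase gene Atp5pb by 1.13 ± 0.11, Txnrd1 by 1.07 ± 0.11 and Rap1a by 1.07 ± 0.10. Below 0 stood Bcl2l12 at -1.34 ± 0.09, the translation initiation gene Eif4b at -1.12 ± 0.08, Safb at -1.03 ± 0.09, Hddc3 at -0.94 ± 0.16 and the myosin gene Myh9 at -0.92 ± 0.08. Wars2 was at -0.92 ± 0.13, Rab21 at -0.85 ± 0.08, Agap2 at -0.80 ± 0.12, Mapk1ip1 at -0.79 ± 0.11 and Nckipsd at -0.75 ± 0.08. Among plasma cell genes 3 of 16 differed upward (7 higher and 0 lower adjusted over the list alone), with Mzb1 at 0.79 ± 0.10 and Xbp1, a regulator of secretion, at 0.59 ± 0.06, each losing its call without 1 array (limma adjusted p from 0.0773 to 0.101). For plasma cell genes, camera gave adjusted p = 0.00478 with the preset correlation and adjusted p = 0.415 with an estimated correlation. The activation and antigen presentation list differed with 2 members higher of 20 (5 higher and 0 lower adjusted over the list alone). For the activation list, camera gave adjusted p = 0.0408 with the preset correlation and adjusted p = 0.860 with an estimated correlation. Ribosome biogenesis genes differed in 3 of 29 (4 higher and 1 lower adjusted over the list alone). For ribosome biogenesis, camera gave adjusted p = 0.0279 with the preset correlation and adjusted p = 0.896 with an estimated correlation. Without 1 array the 391 fell to 91 and 63 (replicates 1 and 2 labelled Ptger4-/-, anti-IgM), 252 and 48 (Ptger4+/+, anti-IgM), 31 for either PGE2 array labelled Ptger4-/- and 63 for either array between the genotypes. Leaving out 1 of the 4 compared arrays ended the calls of Il17ra, Atp5pb, Txnrd1, Rap1a, Hddc3, Wars2, Rab21, Agap2, Mapk1ip1 and Nckipsd (limma adjusted p from 0.0501 to 0.201), and a fit without the dye term made 7 calls in all. A fit of only the arrays compared, with no dye term, made 0 calls, with its unadjusted count given with the processing below. Asking for the minimum fold of limma's treat left 1 call. Without the dye term, 16 of the 20 named genes were not called, Cd74 (limma adjusted p = 0.0872) and Cdk4 (0.147) among them, the exceptions being Ddx3x, Plagl2, Bcl2l12 and Eif4b. Mzb1 and Xbp1 were not called either (0.0946 and 0.135), nor was the activation list by camera (adjusted p = 0.107).

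With PGE2, given with anti-IgM for 24 h, more genes were called lower than higher in Ptger4+/+ cells, Eef1g, Rpl5, Nfkb1 and Psma6 among the lower ones. The comparison asks how PGE2 changes B cell receptor stimulation in cells that carry its receptor. The translation elongation gene Eef1g had a log2 ratio of -2.33 ± 0.06, the ribosomal protein gene Rpl5 of -2.01 ± 0.10 and the initiation factor gene Eif3b of -1.82 ± 0.06 (standard error, n = 2 arrays). Nfkb1, which encodes an NF-kB subunit, stood at -1.97 ± 0.08, the proteasome gene Psma6 at -1.92 ± 0.06, the co-chaperone gene Dnajc7 at -1.84 ± 0.06 and the mitochondrial phosphate carrier gene Slc25a3 at -1.84 ± 0.10. Arfgef1 (-2.01 ± 0.32) was at least 2-fold lower on both arrays, reaching -3.01 on 1 of them. Tmem109 (-3.78 and -0.26 on the arrays) and Cox7a1 (-3.13 and -0.52) also passed but rested mainly on 1 array, and Tmem109 lost its call without replicate 1 (limma adjusted p = 0.154), without the dye term (0.0881) and with scaling (0.068). Rises were smaller: Rasd1, a Ras-like gene, stood at 1.33 ± 0.05, the interleukin-1 decoy receptor gene Il1r2 at 1.27 ± 0.07, Pnmal1 at 1.27 ± 0.07 and the chromatin organiser gene Satb1 at 1.25 ± 0.07. Ptk7 rose by 1.18 ± 0.06, Ly6a, a surface antigen gene, by 1.10 ± 0.08, Pcdhb5 by 1.08 ± 0.14 and Rac3 by 1.02 ± 0.04. Syngr2 rose by 1.02 ± 0.09 and Ddit4, an inhibitor of mTOR signalling, by 1.01 ± 0.09. These 20 genes had limma adjusted p up to 0.0482, that of Tmem109. limma called 2053 of 22533 features higher and 3835 lower, while 7 were at least 2-fold higher and 149 at least 2-fold lower on both arrays (15 in all with 1 array unturned). With arrays scaled to the same spread, 0 were at least 2-fold higher and 65 lower on both, a count without a test. limma then called 894 higher and 2860 lower, and without the dye term 577 and 2329. Only the arrays compared, with no dye term, gave fewer calls still, as given with the processing below. Without replicate 1 the total was 3874 and without replicate 2 it was 2663, where all arrays gave 5888.

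Among genes of the G1-S transition and DNA replication, 23 of 34 measured fell with PGE2 in Ptger4+/+ cells and none rose (0 higher and 24 lower adjusted over the list alone), with the helicase genes Mcm4 at -1.33 ± 0.06 and Mcm6 at -0.77 ± 0.04. Camera gave adjusted p = 2.34e-10 with the preset correlation and adjusted p = 0.270 with an estimated correlation. Ribosome biogenesis and Myc target genes fell in 23 of 29 cases (0 higher and 25 lower adjusted over the list alone), with Gnl3 at -1.55 ± 0.10 and the small nucleolar RNA protein gene Nop56 at -1.36 ± 0.09. For ribosome biogenesis, camera gave adjusted p = 1.66e-10 with the preset correlation and adjusted p = 0.375 with an estimated correlation. Genes of heat shock and protein folding fell in 11 of 16 cases (0 higher and 13 lower adjusted over the list alone). For heat shock genes, camera gave adjusted p = 7.34e-07 with the preset correlation and adjusted p = 0.375 with an estimated correlation. NF-kB targets fell in 14 of 21 cases and rose in 1 (1 higher and 15 lower adjusted over the list alone), with Icam1 at -1.24 ± 0.05 against Bcl3 at 0.47 ± 0.09, whose call ended without replicate 1 or 2 (limma adjusted p = 0.0581 and 0.112). For NF-kB targets, camera gave adjusted p = 3.40e-06 with the preset correlation and adjusted p = 0.284 with an estimated correlation. Plasma cell genes fell in 10 of 16 cases (0 higher and 10 lower adjusted over the list alone), Mzb1 at -1.12 ± 0.07 and Hspa5 at -0.85 ± 0.08. For plasma cell genes, camera gave adjusted p = 0.00286 with the preset correlation and adjusted p = 0.270 with an estimated correlation. Immediate-early genes fell in 11 of 22 cases (1 higher and 11 lower adjusted over the list alone), Dusp2 at -1.50 ± 0.07 and Ccl3 at -1.27 ± 0.08. For immediate-early genes, camera gave adjusted p = 0.00508 with the preset correlation and adjusted p = 0.375 with an estimated correlation. Activation and antigen presentation genes fell in 8 and rose in 1 of 20 (1 higher and 10 lower adjusted over the list alone), with Cd74 at -1.40 ± 0.04 and Batf at -1.12 ± 0.06. For the activation list, camera gave adjusted p = 0.0183 with the preset correlation and adjusted p = 0.375 with an estimated correlation. Mitosis genes were split, with 12 falls and 3 rises among 31 (5 higher and 12 lower adjusted over the list alone), Mad2l1 at -0.67 ± 0.04 and Cks2 at -0.80 ± 0.05 against Hmmr at 0.60 ± 0.04. For mitosis genes, camera gave adjusted p = 0.0183 with the preset correlation and adjusted p = 0.375 with an estimated correlation. Of 962 measured olfactory, vomeronasal, trace-amine receptor and keratin genes, 127 were called higher and 1 lower in this comparison. Over all 22533 features 2053 were higher and 3835 lower. Whether a weaker specific signal of the Ptger4+/+ RNA with anti-IgM and PGE2 contributed to the falls above was not tested.

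Other lists moved in part with PGE2 in Ptger4+/+ cells. Cholesterol synthesis genes fell in 7 and rose in 2 of 17 (2 higher and 7 lower adjusted over the list alone), with Idi1 at -0.61 ± 0.05 against Dhcr7 at 0.32 ± 0.04. For cholesterol synthesis, camera gave adjusted p = 0.0234 with the preset correlation and adjusted p = 0.518 with an estimated correlation. Genes of p53 signalling and apoptosis fell in 7 and rose in 1 of 22 (1 higher and 7 lower adjusted over the list alone), with Phlda3 at -0.70 ± 0.04 and Mdm2 at -0.58 ± 0.05. For p53 genes, camera gave adjusted p = 0.0225 with the preset correlation and adjusted p = 0.375 with an estimated correlation. Hypoxia and amino acid stress genes fell in 9 of 19 cases and rose in 1 (1 higher and 10 lower adjusted over the list alone). For the hypoxia list, camera gave adjusted p = 0.0241 with the preset correlation and adjusted p = 0.518 with an estimated correlation. Camera made no call for the following lists. Targets of cyclic AMP and CREB rose in 4 and fell in 7 of 24 (5 higher and 7 lower adjusted over the list alone), the cyclic AMP-induced repressor gene Crem at 0.91 ± 0.06 and Pde4b at 0.68 ± 0.06 against Crebbp at -0.68 ± 0.07 and Rgs2 at -0.51 ± 0.07. For cyclic AMP targets, camera gave adjusted p = 0.869 with the preset correlation and adjusted p = 0.898 with an estimated correlation. Quiescence and homing genes rose in 7 and fell in 3 of 22 (7 higher and 4 lower adjusted over the list alone), with S1pr1 at 0.54 ± 0.06 and Tsc22d3, a glucocorticoid-induced gene, at 0.49 ± 0.08, not called without replicate 2 (limma adjusted p = 0.0832). For quiescence genes, camera gave adjusted p = 0.401 with the preset correlation and adjusted p = 0.518 with an estimated correlation. B cell identity genes rose in 4 and fell in 4 of 20 (4 higher and 6 lower adjusted over the list alone), with Cd79a at 0.92 ± 0.06, Cd22 at 0.79 ± 0.08 and the adaptor gene Blnk at -0.65 ± 0.05. In the prostaglandin pathway 4 of 19 fell (0 higher and 4 lower adjusted over the list alone), including Ptger2, another PGE2 receptor gene, at -0.61 ± 0.05, the thromboxane receptor gene Tbxa2r at -0.71 ± 0.06 and Ptger4. Regulators of MAPK and B cell receptor signalling fell in 9 of 27 cases (camera adjusted p = 0.0642, and a lower call at 0.0399 without the dye term), glycolysis genes fell in 7 and rose in 1 of 18, and JAK-STAT genes fell in 4 and rose in 2 of 18. Interferon response genes fell in 3 and rose in 2 of 23, with Isg15 at -0.62 ± 0.06.

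In cells labelled Ptger4-/- the same addition of PGE2 moved few genes past the test. The actin-binding gene Pfn1 had a log2 ratio of -1.41 ± 0.06 (standard error, n = 2 arrays, limma adjusted p = 0.000741), the 1 feature at least 2-fold changed on both arrays (7 with 1 array unturned). Further falls were those of Ywhae at -0.89 ± 0.08, the proteasome activator gene Psme3 at -0.83 ± 0.09, Cd79a at -0.81 ± 0.06, Selenow at -0.76 ± 0.06 and Tomm6 at -0.68 ± 0.08. Ly6e stood at -0.62 ± 0.08, Nabp2 at -0.62 ± 0.05, the haem synthesis gene Cpox at -0.61 ± 0.04 and Prrc2a at -0.61 ± 0.05. Called rises were Prmt1, an arginine methyltransferase gene, at 0.71 ± 0.07 and Svopl at 0.37 ± 0.04. These 12 genes had limma adjusted p up to 0.0489. The values of Irak3 (5.35 and 0.23 on the arrays), Rusc1 (4.94 and 0.04), Dhx38 (2.81 and 0.01), Zfhx2 (2.30 and 0.23) and Neurod1 (2.41 and 0.05) were the largest above 0 among uncalled genes with the same sign on both arrays, and limma adjusted p began at 0.381. Over the lists fixed in advance, the called members were Dhcr7 at -0.42 ± 0.04, Cd79a and Tgfb1 at -0.50 ± 0.05, all falls. Camera called cholesterol synthesis genes lower (4 of 17 adjusted over the list alone, adjusted p = 0.000491 with the preset correlation and adjusted p = 0.596 with an estimated correlation). Lower calls with an adjusted p of 0.0299 to 0.0472 also came for 7 lists (p53 and apoptosis, MAPK and B cell receptor regulators, JAK-STAT, glycolysis, quiescence and homing, B cell identity and immediate-early genes), with adjusted p = 0.554 to 0.703 with an estimated correlation. DNA replication genes had a median log2 of -0.01. limma called 2 features higher and 31 lower of 22533, and 1880 stood at an unadjusted p under 0.05, where chance gives 1127. Leaving out an array moved the 33 calls to 96 (its own replicate 1), 47 (its own replicate 2, 42 of them higher), 8 (either anti-IgM array labelled Ptger4-/-) or 1 (either array between the genotypes), and without 1 of its own arrays each named call but those of Pfn1 and Nabp2 was lost (limma adjusted p from 0.0598 to 0.524), as were those of Dhcr7 (0.0887 and 0.155) and Tgfb1 (0.116 and 0.064). Without the dye term limma made 7 calls, and Prmt1, Svopl, Psme3, Tomm6, Ly6e, Nabp2 and Prrc2a were not among them (adjusted p from 0.11 to 0.693). Scaling the arrays gave 154 calls, 24 higher and 130 lower, and using only the arrays compared, without dye term, gave 0 by limma (378 at an unadjusted p under 0.05). NF-kB targets were called lower by camera without the dye term (adjusted p = 0.0422 against 0.0795).

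The PGE2 responses of the genotypes differed in the test of the difference itself. It passed for 2852 features, 2102 of them higher and 750 lower in cells labelled Ptger4-/-, and the responses had r = 0.04 and rho = 0.16 across 22533 features. The PGE2 arrays labelled Ptger4-/- had r = -0.219 with each other (0.0748 with the dye effect removed). Eef1g differed by 2.41 ± 0.09 (log2, standard error, 2 arrays against 2), Rpl5 by 2.34 ± 0.14, Slc25a3 by 2.03 ± 0.14, Psma6 by 1.99 ± 0.09 and Bccip by 1.98 ± 0.13. Dnajc7 differed by 1.87 ± 0.09, Bcl2a1c by 1.87 ± 0.10 and the initiation factor gene Eif3m by 1.87 ± 0.10. Below 0 were Cd79a at -1.72 ± 0.09, Pnmal1 at -1.58 ± 0.10, Pfn1 at -1.52 ± 0.08, Ptk7 at -1.47 ± 0.09 and Selenow at -1.40 ± 0.09. Rasd1 stood at -1.35 ± 0.06, the transporter gene Slc22a4 at -1.32 ± 0.07, Scgb1b27 at -1.27 ± 0.08 and Il1r2 at -1.21 ± 0.09. Those 17 genes had limma adjusted p up to 0.000657. Arfgef1 at 2.46 ± 0.46, Hnrnpf at 2.09 ± 0.39 (1.76 and -0.11 on the PGE2 arrays labelled Ptger4-/-) and Pcdhb5 at -1.28 ± 0.20 passed too, and each lost its call without 1 array (limma adjusted p = 0.114 for Arfgef1 without replicate 2 of the PGE2 arrays labelled Ptger4-/-, 0.0914 for Hnrnpf without replicate 2 of the Ptger4+/+ PGE2 arrays and 0.068 for Pcdhb5 without replicate 1 of those labelled Ptger4-/-). DNA replication genes differed upward in 20 of 34 cases (22 higher and 0 lower adjusted over the list alone), Mcm4 by 1.32 ± 0.08 and Mcm6 by 0.73 ± 0.06. For DNA replication, camera gave adjusted p = 1.72e-11 with the preset correlation and adjusted p = 0.235 with an estimated correlation. Ribosome biogenesis genes did so in 16 of 29 (23 higher and 0 lower adjusted over the list alone). For ribosome biogenesis, camera gave adjusted p = 1.72e-11 with the preset correlation and adjusted p = 0.390 with an estimated correlation. Heat shock genes did in 9 of 16 (9 higher and 0 lower adjusted over the list alone). For heat shock genes, camera gave adjusted p = 1.74e-07 with the preset correlation and adjusted p = 0.390 with an estimated correlation. NF-kB targets did in 8 of 21, with 1 lower (13 higher and 1 lower adjusted over the list alone). For NF-kB targets, camera gave adjusted p = 8.53e-06 with the preset correlation and adjusted p = 0.317 with an estimated correlation. Plasma cell genes differed upward in 6 of 16 (8 higher and 0 lower adjusted over the list alone). For plasma cell genes, camera gave adjusted p = 0.00163 with the preset correlation and adjusted p = 0.235 with an estimated correlation. Camera also called the immediate-early (adjusted p = 0.0161), activation (adjusted p = 0.0264) and hypoxia lists (adjusted p = 0.0443), with adjusted p = 0.469, 0.443 and 0.618 with an estimated correlation. Mitosis genes were called higher by camera without the dye term (adjusted p = 0.0456 against 0.0538). Targets of cyclic AMP and CREB, not called by camera, had 4 higher and 2 lower of 24 (6 higher and 3 lower adjusted over the list alone), with Crebbp at 0.55 ± 0.10 and Rgs2 at 0.47 ± 0.09 against Crem at -0.82 ± 0.08 and Pde4b at -0.55 ± 0.09. Of these 4 genes all but Crem lost their calls without 1 array (limma adjusted p from 0.0534 to 0.112), and Crebbp and Rgs2 also without the dye term (0.205 and 0.238). Of the 962 olfactory, vomeronasal, trace-amine receptor and keratin genes, 31 were lower and 1 was higher in this difference. The share lower was near that of all features, 750 of 22533, where 2102 were higher. Without replicate 1 or 2 of the PGE2 arrays labelled Ptger4-/- the count was 1304 or 1096, and without replicate 2 of the Ptger4+/+ PGE2 arrays it was 1671. It was 1111 without the dye term, where Hnrnpf and Pcdhb5 lost their calls (limma adjusted p = 0.0648 and 0.113), 1826 with scaling and 167 with only the arrays compared and no dye term.

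**Figure D2:**
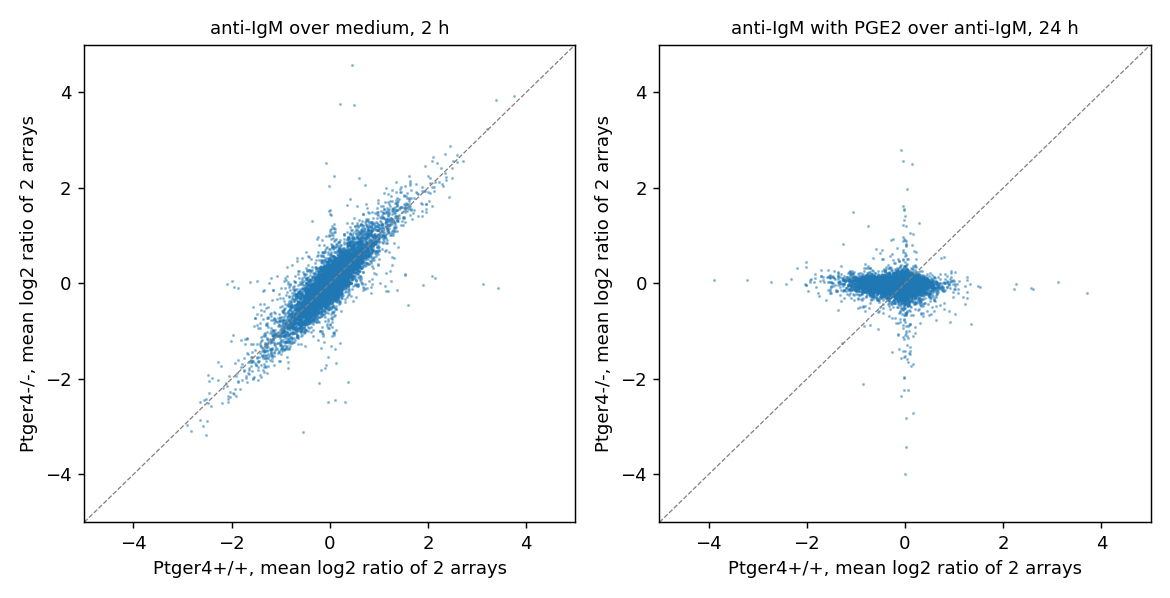
Log2 ratio of every feature in Ptger4+/+ cells (horizontal axis) against cells labelled Ptger4-/- (vertical axis), for anti-IgM at 2 h and for PGE2 at 24 h, with both axes limited to 5 units either side of 0. The anti-IgM responses had r = 0.85 and the PGE2 responses r = 0.04, where the PGE2 arrays labelled Ptger4-/- had r = -0.219 with each other.

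With anti-IgM and PGE2 present for 24 h, cells labelled Ptger4-/- had higher levels than Ptger4+/+ cells of Eef1g, Rpl5, Psma6 and Cd74 and lower levels of Ptk7, Il1r2 and Cd79a. The comparison sets the genotypes side by side under PGE2. It holds the Ptger4+/+ RNA with anti-IgM and PGE2 that the PGE2 comparison of those cells also holds. Opposite signs there are not an independent result. Eef1g had log2 ratios of 2.90 and 3.10 on the arrays. Rpl5 was higher by 2.97 ± 0.10 (log2, standard error, n = 2 arrays), Slc25a3 by 2.74 ± 0.10, Psma6 by 2.66 ± 0.06 and Bccip by 2.58 ± 0.09. Dnajc7 was higher by 2.55 ± 0.06, Eif3m by 2.45 ± 0.07, Atp5pb by 2.40 ± 0.08 and Cd74 by 2.39 ± 0.04. Prkag1 rested mainly on 1 array (0.58 and 4.58). On the lower side stood Spire1 at -1.64 ± 0.18, Ptk7 at -1.57 ± 0.06, Il1r2 at -1.24 ± 0.07, Tmem72 at -1.21 ± 0.08 and Slc22a4 at -1.19 ± 0.05. Cd79a was at -1.18 ± 0.06, Tsga10 at -1.12 ± 0.13 and Rac3 at -1.09 ± 0.04. Atp2c1 (-2.46 and -0.06 on the arrays) and Ssu2 (-0.45 and -1.92) passed as well but lost their calls without 1 array (limma adjusted p = 0.321 for Atp2c1 without replicate 1 and 0.0878 without replicate 2, and 0.203 for Ssu2 without replicate 2). All 20 had limma adjusted p up to 0.0282, that of Prkag1. limma called 3593 features higher and 2476 lower of 22533, and 321 and 13 were at least 2-fold higher or lower on both arrays (14 in all with 1 array unturned). The fewest calls among the alternative fits without a minimum fold came with only the arrays compared and no dye term, as given with the processing below. Without replicate 1 the total of 6069 fell to 2418, without replicate 2 to 2511, and without the dye term to 2749, where Prkag1 and Atp2c1 were not called (limma adjusted p = 0.06 and 0.422).

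Ribosome biogenesis and Myc target genes were higher in cells labelled Ptger4-/- in 23 of 29 cases and lower in 0 (24 higher and 0 lower adjusted over the list alone), with Nop56 at 2.26 ± 0.09 and Gnl3 at 2.05 ± 0.10. For ribosome biogenesis, camera gave adjusted p = 8.36e-12 with the preset correlation and adjusted p = 0.283 with an estimated correlation. NF-kB targets were higher in 14 and lower in 2 of 21 (15 higher and 3 lower adjusted over the list alone), with Nfkb1 at 2.35 ± 0.08 and Icam1 at 1.45 ± 0.05. For NF-kB targets, camera gave adjusted p = 5.34e-05 with the preset correlation and adjusted p = 0.283 with an estimated correlation. For heat shock and folding genes 10 of 16 were higher (10 higher and 0 lower adjusted over the list alone), with Cct3 at 1.96 ± 0.08 and Cct2 at 1.07 ± 0.05. For heat shock genes, camera gave adjusted p = 2.48e-05 with the preset correlation and adjusted p = 0.283 with an estimated correlation. Activation and antigen presentation genes were higher in 11 and lower in 1 of 20 (11 higher and 1 lower adjusted over the list alone), with Batf at 1.67 ± 0.06. For the activation list, camera gave adjusted p = 0.000411 with the preset correlation and adjusted p = 0.283 with an estimated correlation. Among plasma cell genes 9 of 16 were higher and 1 lower (9 higher and 1 lower adjusted over the list alone), with Mzb1 at 1.63 ± 0.07 and the immunoglobulin joining chain gene Jchain at 1.10 ± 0.05. For plasma cell genes, camera gave adjusted p = 0.000411 with the preset correlation and adjusted p = 0.283 with an estimated correlation. DNA replication genes were higher in 13 and lower in 3 of 34 (16 higher and 3 lower adjusted over the list alone), with Mcm4 at 1.34 ± 0.06 and Mcm6 at 0.59 ± 0.04. For DNA replication, camera gave adjusted p = 0.00107 with the preset correlation and adjusted p = 0.283 with an estimated correlation. Interferon response genes were higher in 9 of 23 (12 higher and 1 lower adjusted over the list alone), with the ubiquitin-like gene Isg15 at 2.02 ± 0.06. For interferon response, camera gave adjusted p = 0.0184 with the preset correlation and adjusted p = 0.283 with an estimated correlation. Immediate-early genes were higher in 9 and lower in 1 of 22 (11 higher and 1 lower adjusted over the list alone), with Dusp2 at 1.76 ± 0.07. For immediate-early genes, camera gave adjusted p = 0.00398 with the preset correlation and adjusted p = 0.378 with an estimated correlation. For p53 and apoptosis genes 10 were higher and 1 lower of 22 (12 higher and 1 lower adjusted over the list alone). For p53 genes, camera gave adjusted p = 0.00111 with the preset correlation and adjusted p = 0.283 with an estimated correlation. Cholesterol synthesis genes were higher in 11 and lower in 1 of 17 (12 higher and 2 lower adjusted over the list alone). For cholesterol synthesis, camera gave adjusted p = 0.00582 with the preset correlation and adjusted p = 0.520 with an estimated correlation. In the prostaglandin pathway 5 were higher and 1 lower of 19 (6 higher and 1 lower adjusted over the list alone), with Tbxa2r at 1.68 ± 0.06 and Ptgs2, a key enzyme of prostaglandin synthesis, at 1.04 ± 0.07. For the prostaglandin pathway, camera gave adjusted p = 0.0490 with the preset correlation and adjusted p = 0.283 with an estimated correlation. Crem was lower at -0.75 ± 0.06 within a list of cyclic AMP and CREB targets that camera did not call (5 higher and 4 lower of 24). Beside these groups, 87 of the 962 olfactory, vomeronasal, trace-amine receptor and keratin genes were called lower and 17 higher. Over all 22533 features 2476 were lower and 3593 higher. Among 1743 genes with 2 probes, 152 had both probes called here, where independent probes would give 125. Of the 152 pairs, 58.6% went the same way (exact 95% interval 50.3% to 66.5%, with pairs taken as independent). In the anti-IgM comparison of Ptger4+/+ cells it was 90.9% of 143 (95 with independent probes). Over all 1743 genes the log2 ratios of the probes correlated at r = 0.15 here (rho 0.07). With anti-IgM and with PGE2 in Ptger4+/+ cells r was 0.35 and 0.20. A call of 1 probe thus foretold little about the other here.

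**Figure D3:**
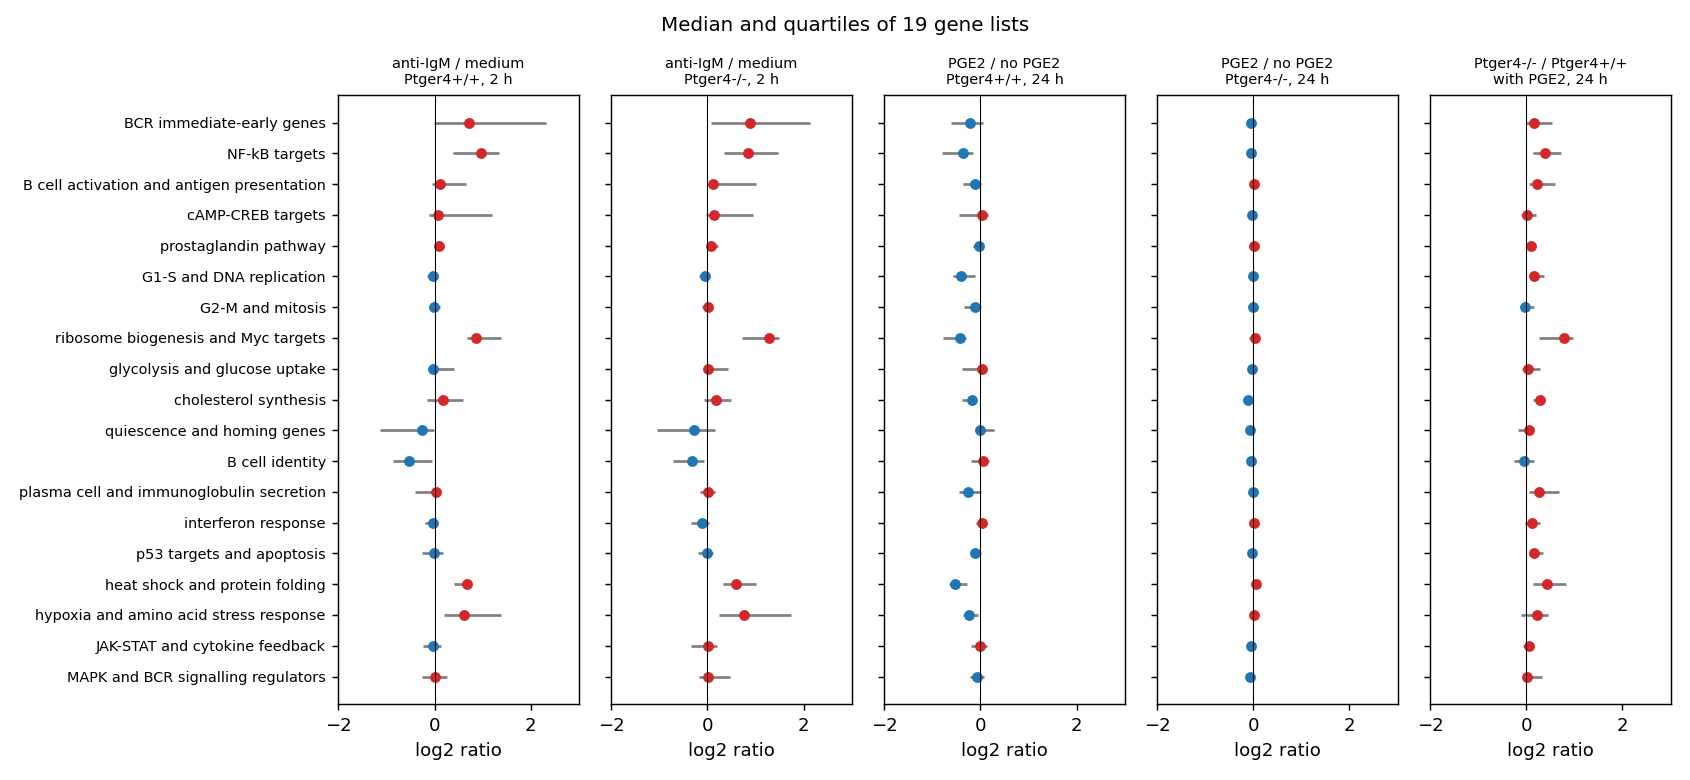
Median log2 ratio (points) and quartiles (lines) of the measured members of each gene list in the 5 comparisons. Ribosome biogenesis and Myc target genes had a median of 0.87 with anti-IgM and -0.43 with PGE2 in Ptger4+/+ cells, and 0.78 between the genotypes with PGE2.

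Cells labelled Ptger4-/- were set against Ptger4+/+ cells with anti-IgM alone by adding up the 3 comparisons of 24 h, since no array held both. Cd74 was the 1 feature called, higher by 1.16 ± 0.07 (log2, standard error, from 6 arrays, limma adjusted p = 0.0117). Isg15 stood at 1.28 ± 0.11 and did not pass (limma adjusted p = 0.0528). Fbxo6, Prkag1, Tmem60 and Map2k5 had larger values above 0, of 4.02, 2.12, 1.80 and 1.56, but with limma adjusted p from 0.615 to 0.694. Lowest values without a call were those of Ppp2r5b at -4.09 ± 2.28, Zfp560 at -2.51 ± 1.11, Dhx38 at -2.34 ± 0.87, Tmem109 at -2.04 ± 1.05 and Cox7a1 at -1.95 ± 0.80. Ptger4 was at -0.14 ± 0.12, with a 95% interval of -0.42 to 0.13. Camera called DNA replication genes lower (median log2 -0.18, adjusted p = 2.45e-08 with the preset correlation and adjusted p = 0.236 with an estimated correlation) and interferon response genes higher (median 0.12, adjusted p = 0.000205 with the preset correlation and adjusted p = 0.236 with an estimated correlation), with 6 of 34 and 3 of 23 members passing when adjusted over the list alone. Mitosis genes had a median of -0.11 (adjusted p = 0.000205 with the preset correlation and adjusted p = 0.274 with an estimated correlation), with 4 of 31 lower adjusted over the list alone. Camera also called cholesterol synthesis, activation, p53 and ribosome biogenesis genes higher (adjusted p = 0.000205, 0.000205, 0.00718 and 0.0268). With an estimated correlation, camera gave these lists adjusted p = 0.362, 0.274, 0.274 and 0.729, in a test that can hardly pass here. Without the dye term camera also called quiescence and B cell identity genes higher (adjusted p = 0.048 and 0.0491 against 0.0802 and 0.0833). Cd74 lost its call without the dye term (limma adjusted p = 1) and with arrays centred and scaled (limma adjusted p = 0.0645). limma placed 1747 features at an unadjusted p under 0.05, where chance gives 1127. Without 1 array the count of 1 became 65 and 31 (PGE2 arrays labelled Ptger4-/-), 21 and 51 (Ptger4+/+ PGE2 arrays), 30 and 12 (arrays between the genotypes) and 0 for any of the 4 anti-IgM arrays (1677 to 1798 at an unadjusted p under 0.05 by limma), each given for replicates 1 and 2 in order.

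Genes that anti-IgM raised at 2 h overlapped with those that PGE2 lowered at 24 h in Ptger4+/+ cells. Of 2188 features raised and 3835 lowered, 1228 were shared, where independent lists share 372 (odds ratio 8.70, 95% interval 7.91 to 9.57, Fisher's exact test). Over all 22533 features, called or not, the responses correlated only weakly (r = -0.18, rho = -0.12). Icam1 and Ccl3 rose with anti-IgM and fell with PGE2, and Mzb1 fell with each. Features lowered by both treatments numbered 822 (436 with independent lists, odds ratio 2.66, Fisher's exact p = 4.68e-89). Those raised by both numbered 68 (199 with independent lists, odds ratio 0.297, Fisher's exact p = 5.92e-31), and those lowered by anti-IgM and raised by PGE2 numbered 247 (233 with independent lists, odds ratio 1.07, Fisher's exact p = 0.325). Features are not independent replicates, and both lists come from the same fit, which shares a spread per feature. The intervals and p-values of these overlaps therefore measure no replication.

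Some members of the marker lists for other cell types were called, in both directions. Expression of these genes in B cells themselves was not examined, so a call alone does not show other cells. With anti-IgM in Ptger4+/+ cells, T cell markers had 1 rise, Cd3g at 0.40 ± 0.05, and 1 fall, Cd2 at -1.48 ± 0.07, among 15 (1 higher and 1 lower adjusted over the list alone). NK markers had 1 rise of 13, monocyte and macrophage markers 2 of 16, neutrophil markers 0 of 11, dendritic cell markers 1 rise and 1 fall of 12, red cell markers 2 and 2 of 10 and platelet markers 1 rise of 8. With PGE2 in Ptger4+/+ cells, T cell markers had 2 rises and 2 falls, NK markers 1 and 1, monocyte markers 2 and 1, neutrophil markers 1 and 0, dendritic cell markers 1 and 2, red cell markers 1 and 2 and platelet markers 1 and 0. In cells labelled Ptger4-/-, anti-IgM lowered Cd2 to -0.63 ± 0.07. Between the genotypes with PGE2, T cell markers had 1 higher, Cd2 at 0.48 ± 0.07, and 2 lower, Cd27 at -0.54 ± 0.08 among them. NK markers had 1 lower, Eomes at -0.41 ± 0.10. Monocyte and macrophage markers had 2 higher, Hmox1 at 0.51 ± 0.08 and Cd68 at 0.20 ± 0.05, and 3 lower, Adgre1 at -0.83 ± 0.05 among them. Dendritic cell markers had 1 higher, Bst2, which interferon also induces, at 1.42 ± 0.05, and 1 lower, Siglech at -0.34 ± 0.07. Neutrophil markers had 1 lower, red cell markers 2 higher, Hbb-b1 at 0.40 ± 0.05 among them, and platelet markers 1 higher. Without replicate 1 the calls of Cd27, Eomes, Siglech and Cd68 ended (limma adjusted p = 0.0639, 0.326, 0.261 and 0.206), and without replicate 2 those of Hmox1 and Cd68 (0.0815 and 0.132). In the difference of the anti-IgM responses, Cd2 was higher (0.85 ± 0.09) and the red cell marker Hba-a1 lower (-0.57 ± 0.07), each losing its call without 1 array (limma adjusted p from 0.0636 to 0.106). In that of the PGE2 responses, Bst2 (1.03 ± 0.07), Ccl22 (0.42 ± 0.08) and Zap70 (0.37 ± 0.09) were higher. Adgre1 (-0.78 ± 0.07), Hba-a1 (-0.49 ± 0.07), Cd27 (-0.48 ± 0.11) and Ccl5 (-0.38 ± 0.09) were lower, and of these 7 all but Bst2 and Adgre1 lost their calls without 1 array (limma adjusted p from 0.0586 to 0.244). Camera called none of the 7 marker lists in the 5 direct comparisons or in these differences, with adjusted p of 0.141 or more.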

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

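All tests of explanations here were chosen only after the result was seen, except that of poor or wrongly annotated probes. The difference between the anti-IgM responses of the genotypes, tested as an interaction with limma, passed for 391 features. Above 0 on the log2 scale, toward cells labelled Ptger4-/-, were Cd74 at 1.66, Cdk4 at 1.33, Ddx3x at 1.28, U2surp at 1.21, Plagl2 at 1.20 and Capns1 at 1.20. Il17ra at 1.14, Atp5pb at 1.13, Txnrd1 at 1.07 and Rap1a at 1.07 followed. Below 0 were Bcl2l12 at -1.34, Eif4b at -1.12, Safb at -1.03, Hddc3 at -0.94 and Myh9 at -0.92. Wars2 at -0.92, Rab21 at -0.85, Agap2 at -0.80, Mapk1ip1 at -0.79 and Nckipsd at -0.75 completed these. Leaving out 1 of the 4 arrays ended the calls of Il17ra, Atp5pb, Txnrd1, Rap1a, Hddc3, Wars2, Rab21, Agap2, Mapk1ip1 and Nckipsd (adjusted p from 0.0501 to 0.201). Without the dye term 7 features were called, and 16 of these 20 genes were not, Cd74 (0.0872), Cdk4 (0.147), U2surp (0.0949), Capns1 (0.082), Safb (0.082) and Myh9 (0.14) included. With only the arrays compared and no dye term, 0 features were called, with the unadjusted count given with the processing below. Asking for the minimum fold of limma's treat left 1 call.

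The PGE2 responses differed between the genotypes for 2852 features, against 1111 without the dye term, 1826 with scaling and 167 with only the arrays compared and no dye term. Above 0 were Arfgef1 at 2.46, Eef1g at 2.41, Rpl5 at 2.34, Hnrnpf at 2.09, Slc25a3 at 2.03 and Psma6 at 1.99. Bccip at 1.98, Dnajc7 at 1.87, Bcl2a1c at 1.87, Eif3m at 1.87 and Ptger4 at 0.63 came next. Below 0 were Cd79a at -1.72, Pnmal1 at -1.58, Pfn1 at -1.52, Ptk7 at -1.47 and Selenow at -1.40. Rasd1 at -1.35, Slc22a4 at -1.32, Pcdhb5 at -1.28, Scgb1b27 at -1.27 and Il1r2 at -1.21 closed the group. Without 1 array Arfgef1, Hnrnpf and Pcdhb5 lost their calls (adjusted p = 0.114, 0.0914 and 0.068).

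Genes measured by 2 probes often had probes that disagreed between the genotypes with PGE2, where 58.6% of 152 called pairs went the same way. Noise of these arrays that is independent between probes is argued against. In the 63 pairs that went opposite ways, the difference between the probes was turned in 98.4% on the separate PGE2 arrays of Ptger4+/+ cells. That was 62 pairs (95% interval 91.5% to 100%), where such noise gives 50%. The intervals and the bound in this paragraph treat pairs as independent, though all share the same arrays, so they measure no replication. Both comparisons hold the Ptger4+/+ RNA with anti-IgM and PGE2, so chance in that RNA is not argued against. A difference between RNA preparations that moves probes rather than genes would give a share such as the 58.6%, below the 90.9% and 86.8% of the anti-IgM comparisons. It may account for part of the calls. For PGE2 in Ptger4+/+ cells, which shares an RNA, 75% of 152 pairs went the same way. For the difference of the PGE2 responses it was 83.7% of 49. For poor or wrongly annotated probes, pairs that went the same way with anti-IgM in Ptger4+/+ cells had 80% the same way here (24 of 30), under the bound of 94.2% set beforehand from cells labelled Ptger4-/-. That bound was badly chosen, because those pairs were picked on a response that correlates at 0.85 with the one giving the bound, and against the 88.1% of the PGE2 comparison of Ptger4+/+ cells (74.4% to 96.0%) the 80% is lower but inside the interval, with the difference untested, so this explanation stays open too, as does an untested change of transcripts with PGE2.

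Olfactory, vomeronasal, trace-amine receptor and keratin genes were taken as mostly silent in B cells, which was not checked. With PGE2 in Ptger4+/+ cells, 127 of 962 were called higher and 1 lower, against 2053 and 3835 of all 22533 features. False calls from noise that is independent between genes on the PGE2 arrays of Ptger4+/+ cells are argued against. On the separate arrays between the genotypes, 90.6% of the 127 were below 0 (95% interval 84.1% to 95%). Of the other 835 genes of the set, 51.9% were below 0 there (48.4% to 55.3%). A weaker specific signal of the Ptger4+/+ RNA with anti-IgM and PGE2, held by both pairs of arrays, may account for the rises. The 127 had a median log2 of -0.12 between the genotypes (95% interval -0.14 to -0.10). These intervals treat genes as independent, though all lie on the same arrays and share an RNA, so they measure no replication. Those 127 were picked for their rise against the same RNA, and all 962 genes had a median of only -0.02. Since both pairs share that RNA, an action of PGE2 in Ptger4+/+ cells stays open, and in cells labelled Ptger4-/- limma called 0 of the 962 with PGE2, but only 33 of all features (1880 unadjusted).

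The Ptger4 probe was higher in RNA labelled Ptger4-/- than in Ptger4+/+ RNA, both with PGE2. Exchanged labels on those arrays would make the comparison follow the PGE2 response of Ptger4+/+ cells, and the correlation across features was -0.77, which argues against it, though the comparisons share an RNA. A lower Ptger4 signal with PGE2 in Ptger4+/+ cells alone may account for the pattern, with a difference between the genotypes of 0.63. The ratio without PGE2, -0.14, did not differ from 0 within its 95% interval of -0.42 to 0.13. Whether the probe lies outside the deleted part stays open, and the genotype was not checked by these data.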

How the results depend on the processing

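No test of explanations is reported here, and dropping features with disagreeing arrays and natural logs were chosen only after the result was seen. No paired analysis was possible because the replicate numbers carry no pairing across comparisons. Centring the arrays, single probes and dropping features with disagreeing arrays left every count of calls within 1.5 times its value. Asking for values on all 10 arrays removed nothing, and averaging each pair to 1 replicate gave no test. In the order WT anti-IgM, labelled Ptger4-/- anti-IgM, WT PGE2, labelled Ptger4-/- PGE2, genotypes with PGE2, anti-IgM difference, PGE2 difference and genotypes without PGE2 (WT for Ptger4+/+), a minimum fold of 1.5 gave 752, 994, 251, 1, 510, 1, 123 and 0 calls by limma (22 at an unadjusted p under 0.05 for the last). For the last 6 in that order, the fit without dye term gave 2906, 7, 2749, 7, 1111 and 0 (503 unadjusted by limma for the 0). Only the arrays compared, without dye term, gave 830, 0 (378 unadjusted by limma), 1543, 0 (1379), 167 and 0 (425). A limit of 0.01 gave 3170, 1, 3284, 10, 1272 and 0 by limma (1747 unadjusted), as stricter by construction. Scaling gave 3754 for WT PGE2, 154 for labelled Ptger4-/- PGE2, 1826 for the PGE2 difference and 3 without PGE2. With only the arrays compared, fewer residual degrees of freedom are left than the 4 of the main fit, by construction. How much of the lower counts this explains was not tested. Nor were the other causes, except for the stricter limits. Leaving out each array gave ranges of 3024 to 4779, 3543 to 5343, 2663 to 5712, 1 to 96, 2418 to 6195, 31 to 435, 1096 to 2831 and 0 to 65 calls by limma for the 8 contrasts, with 1677 unadjusted at the 0.

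The 2-fold counts of 463, 645, 156, 1 and 334 became 1236, 1616, 739, 7 and 982 at 1.5-fold, and 947, 1248, 496, 5 and 731 with natural logs, both looser by construction. Scaling gave 65 for WT PGE2 and 4 for labelled Ptger4-/- PGE2, and the cause was not tested. Of 50 list calls over the 5 comparisons, 0 held with an estimated correlation, while fry made 74 and leaving out arrays 43 to 50. Camera with an estimated correlation has 4 residual degrees of freedom and could hardly pass, so the 0 decides nothing. The causes of the other changes were not tested. With 1 array of each genotype in opposite dye orientation, the anti-IgM correlation was 0.616 and 0.709, and the PGE2 correlation turned to -0.294 and -0.159. In the same orientation they were 0.823 and 0.777, and 0.317 and 0.215. A dye effect of each probe lowers such correlations in opposite orientation and raises them in the same orientation. Removing it raised r within all 5 pairs of arrays, from -0.219 to 0.0748 for the PGE2 arrays labelled Ptger4-/-. How much of the change between orientations it explains was not tested. Of 148 results of named genes, each 1 gene in 1 contrast, 31 lost their call without the dye term, 1 with centring and 5 with scaling. Leaving out each array compared, 54 refits of these ended a call, 17 made one and 349 did neither. Of 373 list examples, 100 lost their call without the dye term, 3 with centring and 41 with scaling, and 255 refits without an array ended a call where 639 did not. None of these reversed. List medians near 0 turned sign in 4 cases. The JAK-STAT list in WT PGE2 did so with centring alone. The MAPK list and the monocyte markers in labelled Ptger4-/- anti-IgM, and the monocyte markers between the genotypes with PGE2, did so with centring and with scaling. Signal over background was not analysed here, so its limits are unknown.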

Other observations

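The gene families here were chosen only after the result was seen. Proteasome subunit genes fell with PGE2 in Ptger4+/+ cells in 35 of 47 measured cases and rose in 1 (median log2 -0.44). Translation initiation factor genes fell in 38 of 51 (median -0.39), respiratory chain genes in 43 of 84 with 1 rise (median -0.22) and ribosomal protein genes in 26 of 75 with 1 rise (median -0.23). Of all 5888 features called in this comparison, 3835 fell. In the same comparison 127 of 962 olfactory, vomeronasal, trace-amine receptor and keratin genes rose and 1 fell, against 2053 and 3835 of all 22533 features. Between the genotypes with PGE2, 17 of these 962 were higher and 87 lower in cells labelled Ptger4-/-, against 3593 and 2476 of all features. Whether a weaker specific signal of the Ptger4+/+ RNA with anti-IgM and PGE2 contributed to the family falls was not tested. The family medians kept their sign with centred and with scaled arrays.

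Between the genotypes with PGE2, 37 proteasome, 34 initiation factor, 51 respiratory chain and 26 ribosomal protein genes were higher in cells labelled Ptger4-/-, and 2, 0, 0 and 1 were lower by limma. Over the whole families, the PGE2 responses themselves differed upward for 28 of 47, 29 of 51, 26 of 84 and 21 of 75 genes and downward for 2, 0, 0 and 1. Both contrasts hold the Ptger4+/+ RNA with anti-IgM and PGE2, as does the PGE2 comparison of Ptger4+/+ cells. The family counts of these contrasts are therefore not independent of each other. In cells labelled Ptger4-/-, limma called 1 proteasome gene with PGE2 and 0 of the other families, but it called only 33 of all 22533 features there (1880 at an unadjusted p under 0.05), so these counts say little about the families. The anti-IgM difference between the genotypes correlated across features with the genotypes with PGE2 at r = 0.41 (rho 0.39) and without PGE2 at 0.18 (rho 0.28), genes not being independent replicates.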
